A study of Mus musculus with 12 samples.

How the data were processed

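Total RNA from the meninges of 12 C57BL/6 mice, 6 treated with DSS and 6 controls, was sequenced by the authors from stranded total RNA libraries, per the labels' protocols. The deposited tables hold 1 column per mouse, and columns were assigned to mice by their heading, which equals each sample's description label; 0 columns belonged to no sample. Per the submitters' processing notes, the tools were CASAVA, FastQC, Trim Galore, HISAT2 and featureCounts with the mm10 build; their versions, the gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes of near-identical copies, such as Hbb-bs, the schlafen, Oas and MHC class I genes, histone genes and immunoglobulin genes, and overlapping or antisense genes, are therefore uncertain where reads are shared.

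The first deposited table holds whole-number counts per gene symbol as the authors made them, not normalized. The second deposited table is a normalized signal: tested on the values, each column is the count column divided by a single factor, and the factors equal the median-of-ratios size factors computed from the counts. The count table was used for all main tests. Of its 47747 symbols, 45251 (94.8%) were found in GENCODE release M21 on GRCm38, the assembly that mm10 denotes.

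Changed genes were called with edgeR 4.0.16 in R 4.3.3: filterByExpr with a minimum count of 10 and a minimum total of 15, TMM factors, and the quasi-likelihood F-test (glmQLFit and glmQLFTest) with treatment as the only term, two-sided, at a Benjamini-Hochberg adjusted p under 0.05. Standard errors of log2 fold changes are the absolute log2 fold change over the square root of F. CPM values use TMM library sizes, and log2 CPM a prior count of 2. The p-values of single genes measure the spread between mice, which the series design counts as 12 animals. Before the data were examined, 48 gene lists of cell types, responses and technical signals were fixed. The 46 with at least 5 tested members were tested with camera in limma 3.58.1 with a preset inter-gene correlation of 0.01, adjusted over the 46 lists. This setting treats list members as nearly independent, so its small p-values do not measure the spread between mice alone. The estimated correlation of the neutrophil list was 0.61. Each list also had camera with an estimated correlation, fry, and an exact two-sided permutation test of its score (mean log2 CPM of its members) over all splits of the mice into 6 and 6, whose smallest possible p is 0.00216. Library measures were compared by the same exact permutation test.

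Genes named in the text were chosen by a rule fixed before the data were examined: the 8 risen and 8 fallen genes with the smallest p among called genes with a mean log2 CPM of at least 1 and no predicted, Rik or accession-style name, up to 4 members with the smallest p of each list called by camera, and always Lcn2, S100a8, S100a9, Saa3, Igha, Jchain, Cldn5, Fkbp5, Hbb-bs and Mki67. In GENCODE M21 on GRCm38, Lcn2 lies on chromosome 2 from 32384633 to 32388252, S100a8 on chromosome 3 from 90668978 to 90670035, S100a9 on chromosome 3 from 90692632 to 90695721, Mpo on chromosome 11 from 87793581 to 87804413, Per2 on chromosome 1 from 91415982 to 91459324, Npas2 on chromosome 1 from 39193731 to 39363236, Kif5c on chromosome 2 from 49619298 to 49774778 and Acp5 on chromosome 9 from 22126727 to 22135711. Counts are per whole gene, so no exon is singled out.

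The steps were tested on 5 simulated data sets drawn from the means and library sizes of these 18593 genes for DSS against Control. Genes changed 1.5-fold were called in 50% of cases, 2-fold in 75.2%, 4-fold in 92.8% and 8-fold in 94.8%; of 91915 unchanged genes 37 were called. A list shifted 1.5-fold was called in 5 of 5 sets and 0 of 223 unshifted lists were called; the simulated genes vary independently, which real genes do not. Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, limma-voom with quality weights, limma-trend on log2 of the deposited normalized values with a pseudocount of 1, robust dispersion, no filter except at least 1 count, a CPM of at least 1 in 6 libraries, 1 surrogate variable from sva 3.50.0, the replicate number as a block, a test against a fold of 1.2, an adjusted p under 0.1, and each mouse left out in turn. All 12 libraries stayed in the main tests. The depth of 9312788 to 41869997 counts per mouse sets the counting error, and the spread between mice the error of each comparison.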

Results

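Gene expression was measured by total RNA sequencing in the meninges, the membranes that cover the brain, of 12 C57BL/6 mice. Dextran sulfate sodium (DSS), a polymer that injures the colon epithelium and is used to induce colitis, had been given to 6 of the mice at 2% in the drinking water for 5 days, and the other 6 were controls. Culling was after 6 days, without the labels saying from which day this was counted. The comparison asks whether gene expression in the meninges differs between mice with and without DSS colitis. Each mouse gave 1 library, with 9312788 to 41869997 counts over 47747 gene symbols. Of these symbols, 18593 passed the filter on low counts. The number of counts did not differ between the groups beyond the spread between mice (25904700 ± 11565700 in controls and 22562800 ± 5489810 in DSS mice, SD, n = 6 each; exact permutation test, p = 0.537). Libraries of the same group were distinct samples: over the 30 pairs, Spearman correlations lay between 0.967 and 0.987, and the lowest chi-square per degree of freedom was 19.1.

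The libraries carried the genes of a fibroblast-rich membrane rather than of colon, which the labels give as the source while titles and extraction protocol name meninges. Col1a1, the main fibrillar collagen gene, lay between 4164 and 9121 CPM (counts scaled to a common library size) in all libraries, and Dcn, which encodes decorin, between 604 and 951 CPM. The border-associated macrophage receptor gene Mrc1 lay between 152 and 271 CPM. Genes of the colon epithelium were low beside these: Epcam lay between 0.159 and 2.03 CPM, Vil1 between 0.199 and 1.17 CPM and the goblet cell mucin gene Muc2 between 0.0800 and 5.62 CPM, and Cdx2 had 0 counts in every library, while Lgals4, a galectin gene of the gut epithelium, lay between 2.71 and 6.24 CPM. All 18 fibroblast genes listed in advance passed the filter, against 8 of 21 colon epithelium genes. Bone genes were present as well. The bone list had a mean log2 CPM of 6.66 in controls and 6.11 in DSS mice, and Col1a1 is also counted here among osteoblast genes. Other tissues were present unevenly. The skeletal muscle list had a mean log2 CPM of 4.13 in DSS replicate 2 and between -0.92 and 0.33 in the other DSS mice. Controls lay between 0.33 and 1.28, and 4 of 6 DSS mice lay below the lowest control. The choroid plexus list varied in both groups (5.41 ± 1.85 in controls, 5.53 ± 1.73 in DSS mice, SD, n = 6). In Control replicate 2, 18S and related ribosomal RNA features took 59.8% of all counts, against 0.194% to 9.23% in the other controls and 0.0430% to 2.76% in DSS mice. The difference in this share between groups was within the spread (exact permutation p = 0.0801, adjusted over 6 library measures p = 0.481).

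DSS mice had higher expression of genes of neutrophils, their precursors and monocytes, of interferon-stimulated and cell-cycle genes, and lower expression of a smaller set of genes. Clock genes went in both directions. Of the 23 gene lists called by camera with a preset correlation, 0 were called with an estimated correlation (lowest adjusted p = 0.0829). In all, 919 of the 18593 tested genes changed, of which 684 rose and 235 fell, and 218 rose more than 2-fold against 42 that fell more than 2-fold. The 8 risen genes with the smallest p among those with a mean log2 CPM of at least 1 were Rac2, Cd52, Slfn4, Csf3r, Hk3, Slfn1, Myo1f and Ncf1, most of them expressed in myeloid cells. Slfn4, a schlafen gene of myeloid cells, rose 9.76-fold from 1.73 ± 0.305 to 16.5 ± 6.27 CPM (SD, n = 6; log2 fold change 3.29 ± 0.30 SE, adjusted p = 0.000144). Rac2 and Ncf1, which encode subunits of the phagocyte NADPH oxidase, rose 2.12-fold and 2.84-fold. The 8 fallen genes were Kif5c, Id2, Npas2, Gpnmb, Tspyl4, Fzd8, Acp5 and Plat. Kif5c, a neuronal kinesin gene, fell by 0.92 on the log2 scale (SE 0.12, adjusted p = 0.000622), from 101 ± 13.5 to 53.4 ± 9.14 CPM, and Plat, which encodes tissue plasminogen activator, from 91.0 ± 5.93 to 62.9 ± 7.93 CPM. In each of these 16 genes all 6 DSS mice lay beyond the most extreme control, as in 376 of the risen and 95 of the fallen genes. Chance gives such a separation in a given direction for 0.108% of genes without a difference. The genes counted here were selected by their p in the same mice, so their separation describes them and is no separate support.

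These counts are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment at 0.05. The number of changed genes was 538 without DSS replicate 6, 559 without DSS replicate 4, 608 without Control replicate 5 and 1379 without DSS replicate 2, and the number of fallen genes was 151, 112, 147, 115 and 150 without Control replicates 2, 3, 4, 5 and 6 and 141, 390, 97 and 95 without DSS replicates 1, 2, 4 and 6. Leaving out Control replicate 2 and DSS replicate 2 together, a setting chosen after the data were seen, gave 1152 genes (852 risen, 300 fallen), 788 of them among the 919.

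Neutrophil genes rose in DSS mice. Of the 20 tested members of the neutrophil list, 19 rose (19 also when adjusted over the list alone), with a median log2 fold change of 3.16. Lcn2, which encodes the siderophore-binding granule protein lipocalin 2, rose 13.7-fold, from 7.33 ± 3.29 to 96.9 ± 45.0 CPM (SD, n = 6; log2 fold change 3.78 ± 0.41 SE, adjusted p = 0.000199). Ltf, the lactoferrin gene, rose 9.89-fold and Cd177, a neutrophil surface glycoprotein gene, 10.9-fold, and Csf3r, the receptor gene for granulocyte colony-stimulating factor, rose 3.18-fold. S100a8 and S100a9, the genes of the calprotectin subunits, rose 10.1-fold and 10.4-fold. The 1 member that fell, Mmp9 (log2 fold change -0.40, adjusted p = 0.0350), is named here after its values were seen. It encodes a gelatinase made by neutrophils and osteoclasts, and its call was kept only without Control replicate 6, DSS replicate 3 or DSS replicate 4 among the single mice left out. The list was called by camera (adjusted p = 6.08e-29 with a preset correlation), a call that was lost at adjusted p = 0.0829 with an estimated correlation. The list score was higher in 6 of 6 DSS mice than in any control (exact permutation test, adjusted p = 0.0124, the smallest this design and number of lists gave). DSS replicate 3 had a score of 2.85, against 4.47 to 4.82 in the other DSS mice and 1.25 to 2.40 in controls.

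Genes of granulocyte precursors rose with them. Of 10 tested members of the marrow progenitor list 7 rose (7 adjusted over the list alone), with a median log2 fold change of 2.67. The 3 others were not called, and the lowest log2 fold change in the list was -0.015. The camera adjusted p was 2.11e-09, and adjusted p = 0.0829 with an estimated correlation; the exact permutation adjusted p was 0.0124. Mpo, Elane, Prtn3 and Ctsg encode primary granule enzymes that are transcribed in granulocyte precursors. A list of 7 primary-granule precursor genes, these among them, was taken from the fixed lists after the results were seen. All 7 rose, which repeats the rise of the marrow progenitor list and is no separate support. Mpo rose from 2.68 ± 1.29 to 28.0 ± 13.8 CPM (SD, n = 6; log2 fold change 3.50 ± 0.44 SE, adjusted p = 0.000532), and Ctsg from 0.352 ± 0.163 to 6.14 ± 3.25 CPM. Elane rose 14.5-fold and Prtn3 13.1-fold. Of 14 classical monocyte genes 10 rose (12 adjusted over the list alone). The camera adjusted p was 2.74e-14, and adjusted p = 0.0829 with an estimated correlation (exact permutation adjusted p = 0.0124). Ly6c2, the surface marker gene of inflammatory monocytes, rose 2.80-fold (adjusted p = 0.000199), and Chil3 rose 7.06-fold and Hp, the haptoglobin gene, 9.01-fold. The median log2 fold change of the monocyte list was 1.07. Like the neutrophil score, Chil3 and Hp were lowest among DSS mice in DSS replicate 3. Their log2 CPM there was 4.01 (others 5.71 to 6.28) and 2.56 (others 4.66 to 4.98). With any single mouse left out, 7 marrow progenitor and 9 to 11 monocyte genes rose.

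**Figure D1:**
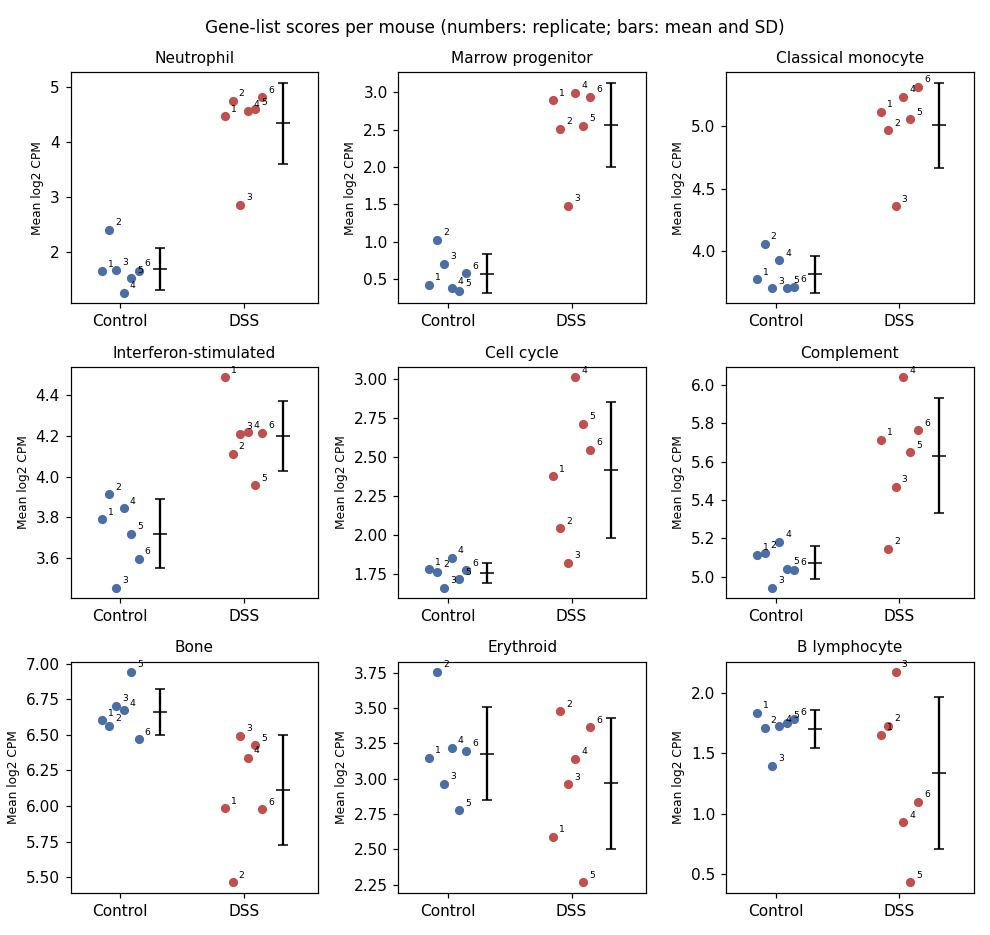
Scores of 9 gene lists in each mouse, as the mean log2 CPM of the list's tested genes (vertical axis), for the 6 control and 6 DSS mice (horizontal axis); points are mice with their replicate number, and bars give the mean and SD of each group. Every DSS mouse lies above every control for the neutrophil, marrow progenitor, monocyte and interferon-stimulated lists, DSS replicate 3 has the lowest neutrophil score of the DSS mice at 2.85, and the erythroid and B lymphocyte scores overlap between groups.

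Lists of other blood and lymphoid cells were not called. None of 14 erythroid, 13 B lymphocyte or 22 T, NK and innate lymphoid genes changed, also when adjusted over the list alone, by edgeR's test, with camera adjusted p = 0.316, 0.250 and 0.163. Fry gave adjusted p = 0.577, 0.551 and 0.577, and 3525 of all tested genes had an unadjusted p under 0.05. The lymphoid lists were low, so changes in them could be missed. The mean log2 CPM of T, NK and innate lymphoid genes was 0.68 in controls and 0.83 in DSS mice. For B lymphocyte genes it was 1.70 and 1.34. Camera called the B lymphocyte list downward without DSS replicate 3 (mean log2 fold change -0.45) and with no filter (-0.28), and the T, NK and innate lymphoid list upward without Control replicate 4 (0.25) or DSS replicate 5 (0.22). Hbb-bs, a beta-globin gene, had a log2 fold change of -0.47 ± 0.34 SE (adjusted p = 0.509). Of 19 plasma cell and immunoglobulin genes 1 rose (1 adjusted over the list alone; camera adjusted p = 0.127): Igha, the constant region gene of immunoglobulin A, from 8.71 ± 4.53 to 27.8 ± 17.6 CPM (SD, n = 6; adjusted p = 0.0426). That call was lost with 9 of the 12 mice left out in turn and kept without Control replicate 3, DSS replicate 2 or DSS replicate 3, with log2 fold changes of 1.35 to 1.90 over all settings. Camera called the plasma cell list upward without DSS replicate 5 (mean log2 fold change 0.71) or 6 (0.69). Jchain, whose product joins IgA dimers, had a log2 fold change of 0.58 ± 0.59 SE (adjusted p = 0.672).

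Interferon-stimulated genes rose by small factors. Of 41 tested members 22 rose and none fell (35 adjusted over the list alone), with a median log2 fold change of 0.46 and a largest of 1.08. Oas2, an oligoadenylate synthetase gene, rose from 4.64 ± 0.823 to 9.89 ± 2.55 CPM (SD, n = 6; log2 fold change 1.08 ± 0.17 SE, adjusted p = 0.00248). Zbp1, which encodes a nucleic acid sensor, rose 1.98-fold and Ifi27l2a 1.69-fold. The camera adjusted p was 2.21e-22, and adjusted p = 0.195 with an estimated correlation; the score was higher in 6 of 6 DSS mice than in any control (exact permutation adjusted p = 0.0124). The number of risen members was 13 without Control replicate 3, 14 without Control replicate 5, and 12 without DSS replicate 1, 4 or 6.

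Cell-cycle genes were higher in DSS mice, with a wider spread than in controls. Of 35 members 15 rose (26 adjusted over the list alone), with a median log2 fold change of 0.81. Mki67, the gene of the Ki-67 antigen of cycling cells, rose 2.60-fold, from 12.7 ± 2.93 to 33.0 ± 12.4 CPM (SD, n = 6; adjusted p = 0.00333), and Ube2c rose 2.33-fold. Top2a, the topoisomerase II alpha gene, rose 2.12-fold (adjusted p = 0.0154), with 4 of 6 DSS mice above the highest control. The camera adjusted p was 3.40e-16, and adjusted p = 0.268 with an estimated correlation; by exact permutation the adjusted p was 0.0181. The number of risen members was 9, 9, 6 and 7 without Control replicates 2, 3, 5 and 6, and 23, 6, 7 and 5 without DSS replicates 3, 4, 5 and 6.

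Innate inflammatory lists were also shifted. Of 19 complement genes 11 rose (12 adjusted over the list alone). The camera adjusted p was 1.83e-09, and adjusted p = 0.268 with an estimated correlation (exact permutation adjusted p = 0.0181). The risen genes included the complement receptor integrin genes Itgam and Itgb2, which rose 2.06-fold and 2.01-fold, C5ar1, the receptor gene for C5a, which rose 2.03-fold, and C4b, which rose from 70.4 ± 3.41 to 142 ± 49.4 CPM (SD, n = 6). The number of risen complement genes was 6, 5, 6 and 6 without Control replicates 1, 3, 4 and 5, and 6, 6, 7 and 5 without DSS replicates 1, 4, 5 and 6. Of 22 NF-kB and pattern-recognition genes 5 rose (10 adjusted over the list alone; camera adjusted p = 2.75e-09, adjusted p = 0.224 with an estimated correlation; exact permutation adjusted p = 0.0124). They included the cytokine gene Il1b, which rose 2.91-fold from 1.65 ± 0.498 CPM, and Nfkbiz, which rose 1.55-fold. Of this list 3 rose without Control replicate 3 or DSS replicate 6, and 8 without DSS replicate 2. Of 24 acute-phase and STAT3 target genes 6 rose (9 rose and 1 fell adjusted over the list alone). The camera adjusted p was 7.47e-06, and adjusted p = 0.283 with an estimated correlation (exact permutation adjusted p = 0.0124). The risen genes included Lcn2 and Hp, which stand in the neutrophil and monocyte lists as well. Others were Socs3, the feedback inhibitor gene of cytokine signalling, which rose 1.59-fold, and Lrg1, which rose 2.40-fold. Of this list 10 rose without DSS replicate 2. Saa3, the serum amyloid gene of macrophages, did not pass the filter, with 0 to 9 counts in control and 0 to 59 counts in DSS libraries. Of 10 mast cell genes 2 rose (5 adjusted over the list alone; camera adjusted p = 0.000913, adjusted p = 0.268 with an estimated correlation; exact permutation adjusted p = 0.0124). Hdc, which encodes the histamine-synthesizing enzyme, rose 2.90-fold and Fcer1a, the IgE receptor gene, 2.07-fold. Hdc stands in the neutrophil list as well, and like the neutrophil score it was lowest among DSS mice in DSS replicate 3 (log2 CPM 1.98, others 3.23 to 3.58). The Fcer1a call was lost without Control replicate 5 (1 member then rose), and 6 members rose without DSS replicate 2. The protease genes Cma1 and Mcpt4 had log2 fold changes of 0.56 ± 0.19 SE and 0.55 ± 0.20 SE (adjusted p = 0.116 and 0.131).

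Macrophage and antigen-presentation lists were called upward, with counts of risen genes that depended on single mice. Of 20 border-associated macrophage genes 4 rose (6 adjusted over the list alone; camera adjusted p = 1.05e-05, adjusted p = 0.451 with an estimated correlation; exact permutation adjusted p = 0.127). They were the complement genes C1qb and C1qc and the lectin genes Clec4n and Siglec1, which rose 1.46-fold to 1.72-fold. Of this list 1 rose without Control replicate 1, 2 without Control replicate 2 or DSS replicate 3, 10 without DSS replicate 2, and 0 without Control replicates 3, 4 or 5 or DSS replicates 1, 4, 5 or 6. Of 18 MHC class II and dendritic cell genes 4 rose (11 rose and 1 fell adjusted over the list alone; camera adjusted p = 5.91e-05, adjusted p = 0.283 with an estimated correlation; exact permutation adjusted p = 0.0613). Ciita, the class II transactivator gene, rose from 13.3 ± 2.81 to 22.6 ± 4.11 CPM (SD, n = 6; adjusted p = 0.00891), and H2-Aa 1.40-fold. Of this list 2 rose without Control replicates 1 or 3 or DSS replicate 5, 1 without Control replicate 5 or DSS replicates 1, 3, 4 or 6, and 9 without DSS replicate 2.

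Clock genes moved in opposite directions. Of 18 circadian clock genes 4 rose and 2 fell (7 and 2 adjusted over the list alone). Per2, a period repressor gene, rose 3.31-fold, from 5.99 ± 1.90 to 19.7 ± 5.62 CPM (SD, n = 6; log2 fold change 1.73 ± 0.25 SE, adjusted p = 0.00143), and Per3 rose 1.68-fold. Dbp and Tef, whose products are clock-output transcription factors, rose by 0.91 and 0.51 on the log2 scale (adjusted p = 0.0384 and 0.0266; both are named after their values were seen). Arntl and Npas2, which encode partner activators of the clock and peak at the opposite phase to Per genes, fell by 0.66 and 1.23 on the log2 scale (SE 0.11 and 0.17, adjusted p = 0.00349 and 0.00123). As a set the list was called upward (camera adjusted p = 0.0271; adjusted p = 0.321 with an estimated correlation; exact permutation adjusted p = 0.0664). That call was lost without DSS replicate 1 or DSS replicate 3 and with the stricter CPM filter, and 2, 2 and 1 members rose without Control replicate 3, Control replicate 5 and DSS replicate 6, against 2 that fell with each mouse left out.

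**Figure D2:**
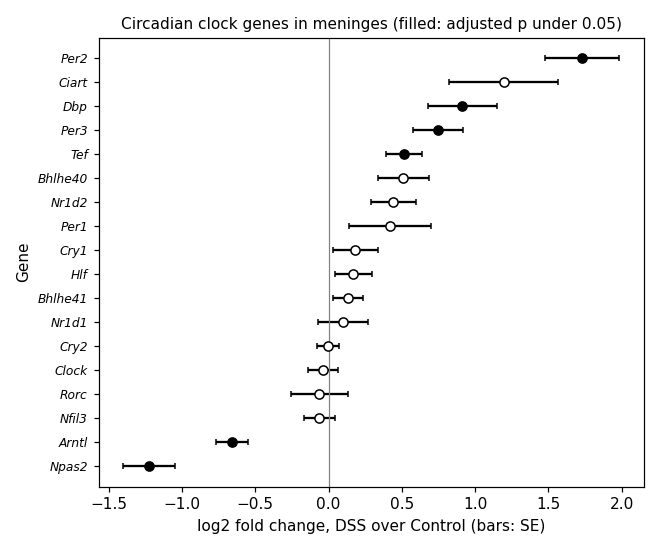
Log2 fold changes of the 18 tested clock genes between 6 DSS and 6 control mice (horizontal axis, DSS over Control, bars give the SE), 1 gene per line; filled points passed edgeR's test at an adjusted p under 0.05. Per2 lies at 1.73 and Npas2 at -1.23.

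Of 28 glucocorticoid-induced genes 5 rose (7 rose and 3 fell adjusted over the list alone; camera adjusted p = 0.00188, adjusted p = 0.459 with an estimated correlation; exact permutation adjusted p = 0.0640). Of the risen genes, Lcn2 and Il1r2 stand in the neutrophil list as well. Pdk4, which encodes a kinase that restrains pyruvate oxidation, rose 1.57-fold (adjusted p = 0.0130). Cdkn1a, the p21 cell-cycle inhibitor gene, rose 1.29-fold (adjusted p = 0.0281), a call lost without Control replicate 3, DSS replicate 4 or DSS replicate 5. Without Control replicate 3, 3 members rose and 1 fell. Fkbp5 had a log2 fold change of 0.30 ± 0.12 SE (adjusted p = 0.199).

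Among lists that were lower in DSS mice, the bone list had 3 fallen genes of 14 (6 adjusted over the list alone; camera adjusted p = 0.000412, adjusted p = 0.363 with an estimated correlation; exact permutation adjusted p = 0.0181). Acp5, the tartrate-resistant acid phosphatase gene of osteoclasts, fell by 1.76 on the log2 scale (SE 0.27, adjusted p = 0.00190), from 141 ± 40.9 to 41.5 ± 20.6 CPM (SD, n = 6), and Ctsk, the osteoclast collagenase gene, from 170 ± 17.3 to 107 ± 29.0 CPM. Ibsp, the bone sialoprotein gene, fell by 1.06 on the log2 scale. The number of fallen bone genes was 1 without Control replicates 2, 3 or 5 or DSS replicates 1 or 6, 2 without Control replicate 4 or DSS replicates 4 or 5, and 6 without DSS replicate 3. Of 18 meningeal fibroblast genes 1 fell (4 adjusted over the list alone; camera adjusted p = 0.00731, adjusted p = 0.282 with an estimated correlation; exact permutation adjusted p = 0.0124). It was Aldh1a2, which encodes a retinoic acid synthesizing enzyme and fell from 58.1 ± 11.5 to 37.7 ± 4.16 CPM (adjusted p = 0.00874). Of this list 2 fell without DSS replicate 2. Of 14 neuron genes 2 fell, Tubb3 and Syn1, with log2 fold changes of -0.69 ± 0.16 SE and -0.82 ± 0.19 SE. In this list 4 fell adjusted over the list alone (camera adjusted p = 2.70e-05, adjusted p = 0.268 with an estimated correlation; exact permutation adjusted p = 0.0581). The number was 3, 1, 1, 0 and 0 without Control replicates 1, 3, 4, 5 and 6, and 1, 6, 3, 3 and 1 without DSS replicates 1, 2, 3, 5 and 6. The astrocyte list was called downward as well, with 1 fallen gene of 11 (3 adjusted over the list alone; camera adjusted p = 0.0315, adjusted p = 0.436 with an estimated correlation; exact permutation adjusted p = 0.180). Gja1, the connexin 43 gene, fell from 170 ± 20.9 to 128 ± 12.9 CPM (adjusted p = 0.0201), a call lost without DSS replicates 1 or 6, and Slc1a2 had a log2 fold change of -0.60 ± 0.19 SE (adjusted p = 0.0894). Of the astrocyte list 3 fell without Control replicate 6 or DSS replicate 2 and 0 without DSS replicate 6, and its camera call was lost without Control replicates 2 or 3 or DSS replicates 3 or 5 (adjusted p = 0.0668, 0.0800, 0.0856 and 0.0505).

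Of 19 vascular endothelium genes 2 rose (2 adjusted over the list alone; camera adjusted p = 0.00940, adjusted p = 0.596 with an estimated correlation; exact permutation adjusted p = 0.199). Ackr1, the atypical chemokine receptor gene of venules, rose 3.32-fold, from a mean of 6.26 to 20.8 CPM (SD of 15.9 CPM among the DSS mice, n = 6; adjusted p = 0.0170), and Eng, the endoglin gene, 1.30-fold (adjusted p = 0.0394). The Eng call was lost without Control replicates 2, 3, 5 or 6 or DSS replicates 1, 4 or 6, each of which left 1 risen member, and the camera call without DSS replicate 2 (adjusted p = 0.103). Cldn5, the tight-junction gene of endothelium, was at 48.9 ± 4.86 CPM in controls and 49.6 ± 12.5 CPM in DSS mice (SD, n = 6; log2 fold change 0.02 ± 0.14 SE, adjusted p = 0.971), a difference whose sign depended on the setting. The tight-junction and vascular-barrier list was not called (camera adjusted p = 0.941). Of its 20 genes 1 fell (1 adjusted over the list alone): Cldn11, a claudin gene of the arachnoid barrier, from 94.9 ± 8.79 to 76.6 ± 4.20 CPM (adjusted p = 0.0200), a call lost without Control replicates 2, 3 or 5, with 0 members then fallen. Cldn11 was also the 1 fallen gene of 11 in the arachnoid barrier list (2 adjusted over the list alone), which camera called downward (adjusted p = 0.00457, and adjusted p = 0.283 with an estimated correlation; exact permutation adjusted p = 0.0809). Of that list 2 fell without Control replicate 6, DSS replicate 1 or DSS replicate 2, and 0 without Control replicates 2, 3 or 5. Cldn11 was the 1 fallen gene of 9 in the oligodendrocyte list too, which camera did not call (adjusted p = 0.405). Its fall can thus not be assigned to the arachnoid barrier alone. Camera did not call the collagen and extracellular matrix list either (adjusted p = 0.867), in which 0 of 40 genes passed edgeR's test.

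The unfolded protein response list was called upward (mean log2 fold change 0.20, camera adjusted p = 0.000533, adjusted p = 0.505 with an estimated correlation). Of its 22 genes 1 rose, Edem1 (6 adjusted over the list alone), with 0 without Control replicates 3 or 5 or DSS replicates 1 or 6, 6 without Control replicate 6 and 5 without DSS replicate 2. The ribosomal protein list was called upward (0.057, camera adjusted p = 0.0117, adjusted p = 0.768 with an estimated correlation), a call lost without Control replicate 1 (adjusted p = 0.295) or DSS replicate 5 (0.169). The pineal gland list was called downward (-0.36, camera adjusted p = 0.0165, adjusted p = 0.540 with an estimated correlation), a call lost without DSS replicate 2 (adjusted p = 0.0651). The cholesterol synthesis list was called downward (-0.12, camera adjusted p = 0.0205, adjusted p = 0.540 with an estimated correlation), a call lost without Control replicate 1 (adjusted p = 0.0556), Control replicate 3 (0.0947), DSS replicate 2 (0.0527) or DSS replicate 3 (0.109). By exact permutation these lists had, in this order, adjusted p = 0.182, 0.727, 0.181 and 0.180. No ribosomal protein, pineal gland or cholesterol synthesis gene was called. Adjusted over the pineal gland list alone, 1 rose and 3 fell.

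Of 46 lists tested, 23 were called, 16 upward and 7 downward. None of the calls held with an estimated correlation (camera, lowest adjusted p = 0.0829, with 5 lists at an unadjusted p under 0.05), whereas fry called 14 lists, 13 of them among the 23, and the exact permutation test of list scores 11, all among the 23. The list called by fry alone was the pituitary list (fry adjusted p = 0.00870, camera adjusted p = 0.0671, adjusted p = 0.268 with an estimated correlation; exact permutation adjusted p = 0.677), which camera called downward without Control replicates 3, 5 or 6 or DSS replicates 2 or 6 (adjusted p = 0.0489, 0.0344, 0.0464, 0.0351 and 0.0262). Of 100 splits of the 12 mice, the real one included, 12 called as many lists as the real groups did.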

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

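The tests in this part were chosen after the results were seen, except the check for samples far from their group. In 318 groups of 6 values (46 list scores, 107 named genes and 6 library measures, in each treatment group), 34 had an extreme mouse further from its neighbour than 0.625 of the group's range. Chance alone gives about 1 in 20 such groups, and list scores and genes overlap, so the flags are not independent.

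DSS replicate 3 accounted for 16 of them. It was the lowest DSS mouse for the neutrophil list (mean log2 CPM 2.85), the monocyte list (4.36, others 4.96 to 5.31) and the marrow progenitor list (1.48, others 2.52 to 2.99). The same mouse was lowest in log2 CPM for Slfn4 (2.40), Csf3r (3.72), Ncf1 (4.43), Ltf (5.38), Cd177 (3.05), Hp (2.56), Lcn2 (4.37), S100a9 (6.23), S100a8 (5.01), Chil3 (4.01), Mpo (2.52) and Hdc (1.98), and highest for Acp5 (6.36, others 4.79 to 5.36).

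DSS replicate 2 stood highest for the skeletal muscle list (4.13) and the share of ribosomal RNA features (2.76%, others up to 0.698%) and lowest for the heat-shock list (5.13) and for the log2 CPM of Per2 (3.07, others 4.40 to 4.53), Socs3 (3.68), Ifi27l2a (3.80), H2-Aa (8.04), C1qb (6.73) and Batf3 (0.15). Control replicate 2 stood highest for the share of ribosomal RNA features (59.8%) and of the 10 most abundant genes (72.5%, others 28.6% to 40.6%), for the neutrophil list (2.40) and for the acute-phase list (4.55). Control replicate 1 was lowest for Syn1 (2.22) and Snap25 (5.82), Control replicate 3 for Ncf1 (3.49) and the B lymphocyte list (1.40), and Control replicate 5 for Hdc (0.88).

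The rise of neutrophil and marrow progenitor genes could come with tissue attached to the meninges, such as skull marrow or blood, and more marrow of unchanged makeup would raise erythroblast genes about as much as the marrow progenitor list. The erythroblast score (8 tested genes, all also in a fixed list, Slc4a1 highest at 6.58 CPM in controls) differed by 0.029 log2 units between the groups (interval of 2 SE either side -0.46 to 0.52; -0.082 to 0.164 with single mice left out), below 1.99 (1.48 to 2.50) for the 10 tested genes of the marrow progenitor list. More blood of unchanged makeup is argued against by the hemoglobin score. It differed by -0.59 (-1.35 to 0.18, and -0.37 without DSS replicate 1), against 2.65 (1.97 to 3.33) for the neutrophil list. Camera gave the hemoglobin list adjusted p = 0.0329, and adjusted p = 0.364 with an estimated correlation. Marrow or blood whose makeup had itself changed under DSS, and neutrophils and precursors within the membranes, cannot be told apart, since no marrow or blood library is among these samples and the marrow progenitor difference of 1.99 (exact permutation p = 0.00216, the smallest this design gives) would look alike from each. The treatment itself stays open as the cause, as a hypothesis.

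Chance was weighed by 100 of the 462 splits of the 12 mice into 2 sets of 6, the real one included. Only 1 of them, the real one, called as many as 919 genes, and the highest other called 79. Chance is thus an unlikely source of the number of changed genes, though 100 splits cannot show a share under 1 in 100. As many as 23 lists were called by camera with the preset correlation in 12 of the 100 splits, with 28 lists in the highest other split, so chance cannot be excluded for the number of called lists.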

How the results depend on the processing

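All alternatives were set before the data were examined, except the joint removal of Control replicate 2 and DSS replicate 2 and the removal of ribosomal RNA features, which gave 1152 and 918 changed genes. Against 919 changed genes (684 risen, 235 fallen), the DESeq2 Wald test called 1563 (1063 and 500) and an adjusted p under 0.1 called 1641, with 634 fallen; these were over 1.5 times the main counts. The test against a fold of 1.2 called 330 (294 and 36), limma-voom with quality weights 479 fallen genes and the fit with no filter 156 fallen genes. For the voom, Wald and unfiltered fits the cause was not tested; the fold test and the looser threshold change the criterion itself. Leaving out each mouse gave 538 to 1379 changed genes, 443 to 989 risen and 95 to 390 fallen. Of the 919 genes, 913 were called by the Wald test, 831 by limma-trend on the deposited normalized values and 891 with DESeq2 size factors. The median log2 fold change of all genes was -0.02 with TMM factors and -0.01 with DESeq2 size factors, and the risen share 74.4% and 78.0%.

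Of 23 lists called by camera, 0 were called with an estimated correlation, 13 by fry (which called 14 lists in all) and 11 by exact permutation; members of a list vary together, which the preset correlation leaves out. Under the other scaling, filters, block and left-out mice, 17 of the 23 kept their call in every setting and 6 lost it in at least 1. None of the 23 changed direction in these settings; of the lists not called, the erythroid list had a mean log2 fold change of -0.14 and of 0.018 without Control replicate 2. The difference in total counts (-3341850) stayed below 0 and on the same side of the threshold with each mouse left out.

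Of 73 named genes past the threshold, 49 kept their call in every alternative and 53 with every mouse left out; 23 lost it against a fold of 1.2, and all 73 kept their direction. Among 34 named genes not past the threshold, the sign turned for Jchain without DSS replicate 1 (-0.18, with a range of -0.18 to 0.86 over left-out mice) and for Cldn5 without DSS replicate 2 (-0.11, range -0.11 to 0.10), with the replicate block (-0.011), with voom (-0.037) and without Control and DSS replicate 2 (-0.12). The cause was not tested.

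Equal replicate numbers did not pair the mice: deviations of same-numbered mice correlated at -0.19 to 0.15, 1 of 6 over 0.1, and 0 of 6 controls correlated best with their own number. With the replicate block 708 genes were called (547 risen, 161 fallen), 631 of them among the 919, with fewer residual degrees of freedom. At this depth and number of mice, simulated 1.5-fold changes were called in 50% of cases, so smaller changes can be missed.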

Other observations

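All tests in this part were chosen after the results were seen, on 15 added gene lists. Each is a description of these mice. Camera p-values of added lists, the hemoglobin list included, were adjusted over these 15 lists alone, which were chosen from these same results. They cannot be set beside the adjusted p-values of the 46 lists fixed in advance. Of the listed genes, 5 of 15 osteoclast, 12 of 16 osteoblast and osteocyte and 16 of 16 corticosteroid genes also stand in lists fixed in advance. Replication-dependent histone genes, which are transcribed in S phase and lack poly(A) tails, rose widely: 32 of 68 (50 adjusted over the list alone) with a median log2 fold change of 0.85 (camera adjusted p = 2.00e-26; adjusted p = 0.0752 with an estimated correlation). Hist1h2ah rose from 6.75 to 19.7 CPM and Hist1h1d from 14.0 to 25.8 CPM, and 27 to 40 histone genes rose with single mice left out. Of 12 MHC class I genes 8 rose (10 adjusted over the list alone; camera adjusted p = 8.22e-12; adjusted p = 0.0752 with an estimated correlation), H2-D1 from 290 to 483 CPM and H2-K1 from 221 to 345 CPM. Of 6 genes of the phagocyte NADPH oxidase 5 rose (6 adjusted over the list alone; camera adjusted p = 8.56e-12; adjusted p = 0.0305 with an estimated correlation), and of 7 eosinophil genes 4 rose (5 adjusted over the list alone; camera adjusted p = 3.75e-05; adjusted p = 0.124 with an estimated correlation), including the granule protein genes Prg2 and Epx by log2 fold changes of 2.04 and 1.97. With single mice left out, 8 to 10 class I, 5 to 6 oxidase and 3 to 4 eosinophil genes rose. Histone and class I genes may share reads with close copies, since the treatment of such reads is not given.

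Melanocyte genes were lower: 4 of 9 fell (4 adjusted over the list alone; camera adjusted p = 0.000107; adjusted p = 0.0371 with an estimated correlation), including Mc1r from 2.58 to 0.808 CPM and Dct from 2.23 to 0.882 CPM; 3 to 4 fell with single mice left out. Of 13 protocadherin alpha genes, which share their constant exons and may thus share reads, 7 fell (13 adjusted over the list alone). Their median log2 fold change was -0.53, and 0 to 12 fell with single mice left out. The camera adjusted p was 1.58e-12, and adjusted p = 0.113 with an estimated correlation. Control means were close for most of these genes, such as 4.67, 4.65 and 4.67 CPM for Pcdha1, Pcdha2 and Pcdha3, as shared reads would give. Pcdha11 and Pcdhac2 were higher, at 6.43 and 8.63 CPM. The count of fallen genes and the camera p may thus largely repeat 1 shared signal. Of 13 nasal gland and odorant-binding genes 5 fell (13 adjusted over the list alone; camera adjusted p = 4.87e-06; adjusted p = 0.223 with an estimated correlation); their score differed by -2.26 log2 units (-1.41 without Control replicate 3, whose score of 6.56 was the highest), and 3 of 6 DSS mice lay below the lowest control. With single mice left out, 0 to 10 of them fell.

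The clock genes of opposite phase could follow the hour at which mice were culled. The score of 11 genes of the Per and Dbp phase minus that of 5 genes of the Arntl phase was higher by 0.92 log2 units in DSS mice (exact permutation p = 0.00433), as a later or earlier hour would give, and the labels give no times, so a difference in hour and an effect of DSS on the clock cannot be told apart. More corticosteroid in DSS mice, which may also raise Per genes, was examined with 16 induced genes outside the clock and neutrophil lists. Their score differed by 0.18 log2 units (interval of 2 SE either side -0.06 to 0.42; exact permutation p = 0.177; 0.12 without DSS replicate 6), with 2 genes risen (3 risen and 1 fallen adjusted over the list alone; 1 to 3 risen with single mice left out). Camera called the list upward (adjusted p = 0.00772; adjusted p = 0.301 with an estimated correlation), and these tests leave that explanation undecided.

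Osteoclast genes were lower: 8 of 14 fell and 1 rose (9 and 1 adjusted over the list alone; 4 to 9 fell with single mice left out; camera adjusted p = 1.12e-05; adjusted p = 0.124 with an estimated correlation). Dilution of the tissue by incoming leukocytes could lower them, but the extracellular matrix score differed by -0.014 log2 units (-0.20 to 0.17) against -0.82 (-1.10 to -0.54) for the osteoclast score. Scores of other non-leukocyte cell lists went both ways. Meningeal fibroblast differed by -0.24, arachnoid barrier by -0.28, astrocyte by -0.27 and neuron by -0.89, but vascular endothelium by 0.19. The differences were -0.10 for pericyte and smooth muscle, -0.008 for lymphatic endothelium and 0.07 for Schwann cells. These values leave open a part for dilution in the lower osteoclast genes, though the extracellular matrix interval lies above the osteoclast interval. Less adherent bone could lower them too, and would lower osteoblast and osteocyte genes alike; that score differed by -0.37 (-0.82 to 0.08; exact permutation p = 0.126; -0.21 without DSS replicate 2), with 2 of 14 genes fallen (5 adjusted over the list alone; 0 to 3 with single mice left out; camera adjusted p = 0.00772; adjusted p = 0.301 with an estimated correlation), which overlaps the osteoclast interval and leaves this open. A change of osteoclasts under DSS may remain as a hypothesis beside it.

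Relations between scores were tested over the 6 DSS mice (2 relations). The cell cycle score and the marrow progenitor score had Pearson r = 0.77 (exact permutation p = 0.0569, adjusted 0.114). Spearman rho was 0.83 (exact permutation p = 0.0583, adjusted 0.117). Cycling precursors would give such a relation, but it did not pass the threshold. Without the 2 mice farthest from the median marrow progenitor score, r was 0.26. That leaves few mice over a narrower range, so it cannot settle whether the relation rests on those 2 mice. Whether the interferon score goes with the neutrophil score is left open by 6 mice (r = -0.10, exact permutation p = 0.650, adjusted 0.650; rho = -0.31, exact permutation p = 0.564, adjusted 0.564; r = -0.63 without the 2 farthest mice).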
